A study of Homo sapiens with 6 samples.

How the data were processed

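Poly(A) RNA sequencing was used to compare HaCaT cells, an immortalised line of human keratinocytes, kept at 37C or exposed to 41C for 1 h per day on 3 days. Each temperature had 3 libraries. Per the labels' protocols, total RNA was isolated with a mirVana kit and libraries were made with a TruSeq Stranded mRNA kit. Trimmomatic 0.36, HISAT2 (version not given in the sources used here) and the genome build GRCh38.p13 are named in the submitters' processing notes. The read counter, its annotation and its strand setting are not given in the sources used here, so reads of genes that overlap on opposite strands may not have been told apart. The sources used here also do not say how long after the last exposure RNA was taken.

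The deposited count table holds whole-number counts of reads per gene symbol, not normalized, for 15379 symbols, and the totals per library ran from 19659112 to 20856144 counts. The deposited FPKM table was made by the authors from the same values. Each nonzero FPKM equalled the count per kilobase of 1 fixed gene length relative to the total count of its own library, within 0.01% for 100% of the values. FPKM is therefore no independent measurement, and it was used for the gene lengths it carries and for alternative tests. Every per-sample column of both tables was used.

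Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, which left 12056, scaled with TMM factors, and tested at 41C against 37C with the robust quasi-likelihood fit and a two-sided test on the 6 libraries. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, at a threshold of 0.05. CPM values (counts per 1e6 counts) are scaled by the TMM factors and given as mean ± SD of 3 libraries, and log2 changes are given ± SE. Group differences of 1 gene cannot reach an exact two-sided permutation p below 0.1 with 3 libraries against 3, so the test relies on the spread shared across genes.

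The comparison, its test, 30 gene lists, the genes to be named and most alternatives were fixed before the data were examined. The lists were drawn from textbook knowledge of keratinocytes, heat stress and the pathways in the series title. Lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 28 lists tested. Camera was repeated with an estimated correlation, and fry tested whether a list's members moved one way on balance. Members were counted past the threshold over all genes and adjusted over the list alone. The named genes were the 12 highest and 12 lowest by fold among genes past the threshold with a mean log2 CPM of at least 1 and non-overlapping groups, up to 4 members per list with the smallest p-values, 21 genes fixed by name, and the 5 genes with the most counts. Other genes named in the text were chosen after their values were seen, and are said to be so.

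Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 and upper-quartile scaling factors in edgeR, no filter, a filter at a CPM of 1 in 3 libraries, a replicate block, each library left out, and limma on log2(FPKM + 1) or log2(FPKM + 0.1). Corrections of each library for its trend on gene length or on GC content (splines with 4 degrees of freedom) were added after the data had been examined, as were the length correction without 37C replicate 3 and camera with an estimated correlation in the other fits. Of the symbols, 15238 (99.1%) matched a gene of GENCODE release 29, which gave GC content and positions on GRCh38. The deposited tables carry symbols and no positions.

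The procedure was tested on simulated data for this comparison, with counts drawn for the 12056 genes at the real means, spread and depths. The edgeR test recovered 34% of genes changed 1.2-fold, 70% of those changed 1.3-fold, 86% at 1.5-fold and 94% at 2-fold, with 6 false calls among 148. It called 0 genes when no change was simulated. Camera found a list planted at 1.2-fold and called 0 others. Genes were drawn independently of each other, whereas the estimated correlation between list members in the deposited counts reached 0.748. The simulation therefore does not show how often camera calls a list of correlated genes falsely. A planted length trend with a Spearman rho of 0.31 was brought to 0.008 by the correction, while false calls were 17 of 157 with the trend and 21 of 165 after its correction.

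The count totals differed little between groups, and the 5 genes with the most counts took 3.42 to 3.71% of each library. Genes with near-identical copies are reported as uncertain, because the handling of reads that fit several copies is not given in the sources used here. SERF1B, chosen after its values were seen, had 6.24, 9.56 and 0.856 CPM in the 3 libraries at 41C, and U2AF1, chosen likewise, had 0.552, 18.9 and 0.456 CPM at 37C. Genes encoded by mitochondrial DNA had no rows in the table and were not analysed here, nor were POMC and HHIP. Some genes that the naming rule takes are not reported here.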

Results

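The series title concerns heat, the ion channel TRPV3, calcium, Hedgehog signalling and factors by which keratinocytes act on pigment cells. The data were gene counts from 3 HaCaT libraries at 37C and 3 at 41C. Totals were 19662115, 19659112 and 19745664 counts in 37C replicates 1, 2 and 3 and 20856144, 20708801 and 20139202 counts in 41C replicates 1, 2 and 3. Libraries of 1 group correlated at 0.992 to 0.995 on the log2 CPM scale, and libraries of different groups at 0.992 to 0.994. By this measure libraries were about as alike across the temperatures as within them. The variation between libraries was a common coefficient of 5.83%. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The first principal component held 29% of the variance and separated the temperatures, with 37C at -1.79 to -13.88 and 41C at 4.97 to 12.58. The second held 25.1% and set 37C replicates 1 and 3 apart, at 14.13 and -14.17.

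The genes that passed the threshold after daily exposure to 41C mostly changed by small folds. Their number does not show how many genes changed, since the test recovered 34% of genes changed 1.2-fold in simulated data. The transcripts that rose included PMEPA1, a target and inhibitor of TGF-beta signalling, the matrix protein genes TNC and COL18A1, the fibronectin receptor subunit ITGA5, the Wnt ligand WNT7A and the secreted chaperone CLU. Those that fell included S100A7 and S100A9, which encode antimicrobial calcium-binding proteins of stressed epidermis, the protease inhibitors SERPINB3 and SERPINB4, and KRT13, a keratin of internal squamous epithelia. PMEPA1 rose 1.68-fold, from 90.6 ± 5.49 to 152.7 ± 15.0 CPM (SD, n = 3; log2 change 0.75 ± 0.07; edgeR adjusted p = 0.000555). S100A7 fell to 0.436 of its 37C level, from 9.80 ± 1.42 to 4.27 ± 1.06 CPM (SD, n = 3; log2 change -1.20 ± 0.17; edgeR adjusted p = 0.00408).

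In all, 131 of 12056 genes passed the threshold of edgeR's quasi-likelihood test, 99 higher (75.6%) and 32 lower at 41C, and 1652 had an unadjusted p under 0.05. The median fold was 1.2 among the higher genes and 0.803 among the lower ones, and 122 of the 131 (93.1%) differed by less than 1.5-fold. In each of the 131 genes the 3 libraries of one group lay above the 3 of the other; 20% of all tested genes did so, against 10% by chance. The 4 genes that differed at least 2-fold all fell, and were S100A7, SERPINB3, TRPV5 and ASMTL-2; the latter was named after its values were seen. TRPV5 rested on 13, 11 and 17 counts against 3, 2 and 4. ASMTL-2 is 1 of several rows whose symbol ends in -2 and that look like second copies of pseudoautosomal genes. What these rows stand for was not tested, so its value is uncertain. The count of 4 was 8, 2 and 20 without 37C replicates 1, 2 and 3 and 0 without 41C replicate 2. With upper-quartile scaling the split was 57 higher and 53 lower (51.8% higher). The count of 131 was 223, 17 and 805 without 37C replicates 1, 2 and 3, and 36, 5 and 41 without 41C replicates 1, 2 and 3. CLU, DYNC1H1, KRT13, MYH9 and PMEPA1 passed in each of these 6 fits; DYNC1H1, the dynein heavy chain gene, was named after its values were seen.

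Other genes at either end of the range belonged to no list. CREG1, which encodes a lysosomal glycoprotein, fell from 308.6 ± 25.7 to 228.4 ± 6.17 CPM (log2 change -0.43 ± 0.05, edgeR adjusted p = 0.00161), and the tight junction gene TJP3 fell to 0.702 of its 37C level. CATSPER2, MCUB, MAPK8IP3, SIGIRR and POMZP3 fell by 0.97, 0.39, 0.38, 0.37 and 0.58 on the log2 scale. POMZP3 arose by fusion of copies of other genes and CATSPER2 has a near-identical pseudogene, so both are uncertain. The epithelial keratin gene KRT80 rose 1.29-fold (0.37 ± 0.06, edgeR adjusted p = 0.00408), as did MYH9, a non-muscle myosin heavy chain gene with 1386 ± 45.7 CPM at 37C (0.37 ± 0.04, edgeR adjusted p = 0.000572), and NAV3 rose 1.37-fold. The 5 genes with the most counts, EEF1A1, SCD, FTH1, GAPDH and ACTB, did not pass, with log2 changes of -0.10, 0.01, 0.07, -0.06 and 0.12.

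**Figure D1:**
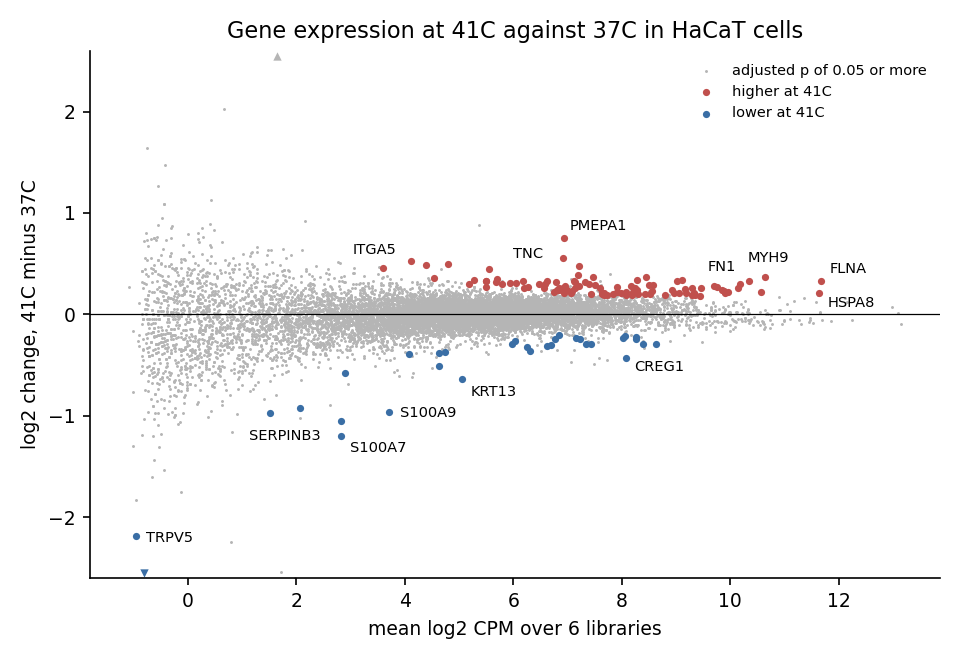
Log2 change at 41C against 37C (vertical) by mean log2 CPM over the 6 libraries (horizontal) for the 12056 genes tested, with the 99 higher genes in red, the 32 lower genes in blue and the rest in grey; triangles mark values beyond the axis. Most changed genes were abundant and lay close to the median change of the higher genes, 0.26, while S100A7, SERPINB3 and S100A9 had log2 changes of -1.20, -1.06 and -0.97 at lower abundance.

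Of 18 tested genes of the basal keratinocyte layer, 9 rose and 0 fell, with a median log2 change of 0.20. LAMA3, which encodes a laminin chain of the epidermal basement membrane, rose 1.29-fold, from 306.2 ± 15.4 to 394.9 ± 18.2 CPM (log2 change 0.37 ± 0.05, edgeR adjusted p = 0.00170). The hemidesmosome collagen COL17A1 rose 1.2-fold (0.26 ± 0.04, edgeR adjusted p = 0.00409) and the growth factor receptor EGFR 1.21-fold (0.28 ± 0.05, edgeR adjusted p = 0.00596). Other members that rose included LAMB3, ITGB4, ITGA3, ITGA6 and KRT14, which were named after their values were seen; 12 were higher and 1 was lower adjusted over the list alone. The list stood above other genes (camera adjusted p = 1.89e-11; adjusted p = 0.0484 with an estimated correlation, and 0.196 with that and the length correction). With an estimated correlation it did not pass in any other fit tried (adjusted p = 0.0536 to 0.376). The 9 higher genes became 2 without 37C replicate 2, 4 without 41C replicate 1 and 0 without 41C replicate 2.

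Of 20 tested genes for matrix proteins and matrix proteases, 7 rose and 0 fell, with a median log2 change of 0.14. They included FN1, the fibronectin gene, from 1157.5 ± 22.7 to 1450.6 ± 49.2 CPM (log2 change 0.33 ± 0.04, edgeR adjusted p = 0.00162), the gelatinase MMP2 (0.32 ± 0.05, edgeR adjusted p = 0.00490), TNC (0.55 ± 0.08, edgeR adjusted p = 0.00498) and the type IV collagen chain COL4A2 (0.27 ± 0.04, edgeR adjusted p = 0.00440). There were 10 higher and 3 lower adjusted over the list alone (camera adjusted p = 4.82e-06, and 0.151 with an estimated correlation). Of the 20 log2 changes 5 were negative, and their mean over the list was 0.09. The count of 7 became 2 without 37C replicate 2 and 0 without 41C replicate 2, and 2 members were lower without 37C replicate 1. SULF2, a matrix sulfatase outside the lists, rose 1.31-fold (0.39 ± 0.05, edgeR adjusted p = 0.00170).

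Of 18 TGF-beta pathway targets 4 rose, among them PMEPA1, TGFBI and SNAI2, and 0 fell, with a median log2 change of 0.20. TGFBI, which encodes a secreted matrix protein, rose from 869.8 ± 17.7 to 1018 ± 49.3 CPM (log2 change 0.23 ± 0.04, edgeR adjusted p = 0.0205), and SNAI2, a transcriptional repressor, rose 1.21-fold (0.27 ± 0.06, edgeR adjusted p = 0.0384). Counts adjusted over the list alone were 7 higher and 2 lower. The lower ones were ID1 (log2 change -0.47 ± 0.13) and ID3 (-0.29 ± 0.08), inhibitors of helix-loop-helix factors named after their values were seen, and neither passed over all genes (edgeR adjusted p = 0.206 and 0.105). The list stood above other genes (camera adjusted p = 0.000538; adjusted p = 0.262 with an estimated correlation). The 4 higher genes became 7 without 37C replicate 3, 1 without 37C replicate 2, 1 without 41C replicate 2 and 2 without 41C replicate 3, and 1 member was lower without 37C replicate 1, 37C replicate 3 or 41C replicate 3.

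**Figure D2:**
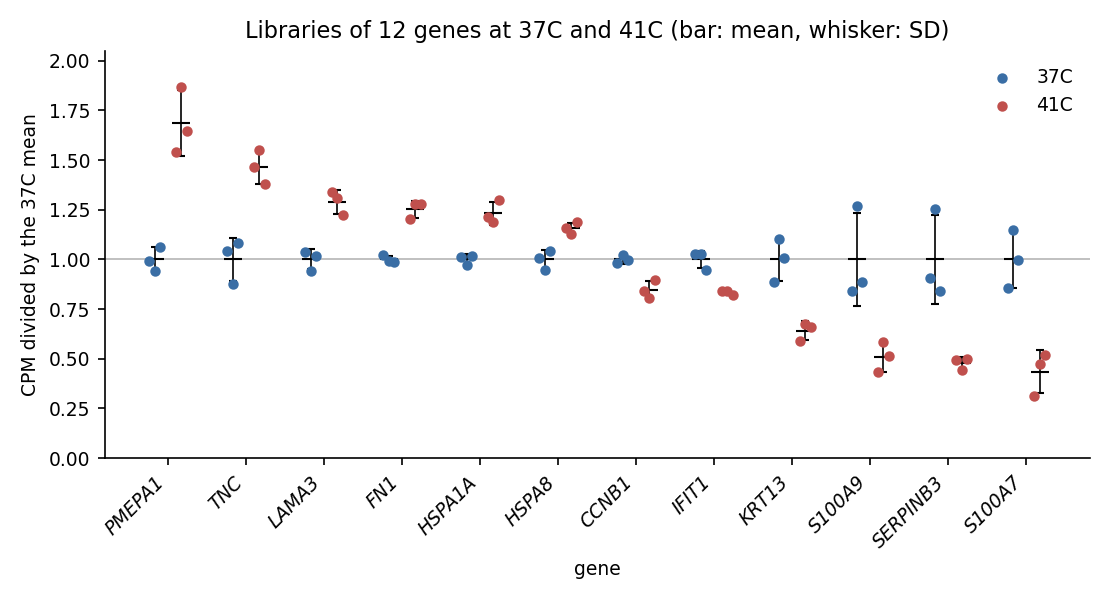
CPM of each library divided by the 37C mean (vertical, linear from 0) for 12 genes, with 37C in blue, 41C in red, and the bar and whisker giving the mean and SD of 3 libraries. The groups of every gene shown were separate, from PMEPA1 at a fold of 1.68 to S100A7 at 0.436.

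Of 26 tested heat shock proteins and co-chaperones, 4 rose and 0 fell, 24 had a positive log2 change, and the median was 0.12. HSPA1A, the inducible HSP70 gene, rose 1.23-fold, from 150.4 ± 3.78 to 185.4 ± 8.64 CPM (log2 change 0.30 ± 0.05, edgeR adjusted p = 0.00498). HSPA8, the constitutive HSP70 gene, rose 1.16-fold from 2957 ± 140 CPM (0.21 ± 0.05, edgeR adjusted p = 0.0364), and the collagen chaperone SERPINH1 and the HSP90 partner FKBP4 rose by 0.20 and 0.21. HSPA1B (0.17 ± 0.05, edgeR adjusted p = 0.108) is nearly identical to HSPA1A, so the separate values of both genes are uncertain. The sum of both rose by 0.24 ± 0.04 (edgeR adjusted p = 0.0159). HSPH1 (0.23 ± 0.06), DNAJB1 (0.14 ± 0.05) and HSP90AA1 (0.17 ± 0.09) did not pass (edgeR adjusted p = 0.130, 0.182 and 0.454). With p-values adjusted over the list alone, 9 were higher (camera adjusted p = 6.03e-08; adjusted p = 0.151 with an estimated correlation). The 4 higher genes became 9 without 37C replicate 3, 1 without 41C replicate 1, 1 without 41C replicate 3, and 0 without 37C replicate 2 or 41C replicate 2.

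Lists of other stress programmes lay slightly below other genes. Among 21 genes of the unfolded protein response of the endoplasmic reticulum, 0 passed over all genes and 1 was lower adjusted over the list alone; the list lay below other genes (median log2 change -0.03, camera adjusted p = 0.00904; adjusted p = 0.293 with an estimated correlation, and 0.0777 with the length correction at the preset one). The median was -0.06 without 37C replicate 1 and -0.08 without 37C replicate 3 or 41C replicate 3. Its chaperone HSPA5 had a log2 change of -0.15 ± 0.04 (edgeR adjusted p = 0.0912). The 21 genes of the integrated stress response also lay below (median -0.08, camera adjusted p = 0.0145; adjusted p = 0.309 with an estimated correlation), with 0 members past the threshold over all genes and 1 lower adjusted over the list alone. That call ended without 37C replicate 1 (0.0509), without 37C replicate 3 (0.165, median -0.03) and with the length correction (0.127). Without 37C replicate 3, 2 unfolded protein response genes and 1 integrated stress response gene were lower. The 16 temperature-sensitive RNA-binding proteins and splicing factors had a median of -0.04 (camera adjusted p = 0.0489; adjusted p = 0.611 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone, with 1 lower without 37C replicate 3. Their call moved with the libraries left out, with camera adjusted p from 0.00111 without 37C replicate 3 (median -0.10; adjusted p = 0.347 with an estimated correlation) to 0.514 without 37C replicate 1 (median -0.02), and 0.130 with the GC correction. The cold-inducible genes CIRBP and RBM3 had log2 changes of -0.09 ± 0.06 and -0.11 ± 0.06 (edgeR adjusted p = 0.522 and 0.392).

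TRPV3, the channel named in the title, gave few counts in these cells. This warmth-gated channel of keratinocytes had 4, 2 and 2 counts at 37C and 2, 10 and 0 at 41C, a ratio of 1.44 with a counting interval of 0.54 to 4.05, so a change of its transcript was not detectable at this depth. TRPV1, the capsaicin receptor, had a log2 change of -0.22 ± 0.09 and TRPV4 one of -0.02 ± 0.07 (edgeR adjusted p = 0.302 and 0.957). TRPV6 and TRPM8 were named after their values were seen. TRPV6 had 3118 counts over the libraries at 37C and 2451 at 41C (ratio 0.75, counting interval 0.71 to 0.79) and did not pass. TRPM8 had 17 and 3 (ratio 0.17, counting interval 0.03 to 0.58), too few to be tested. Of 31 tested genes for TRP channels and calcium signalling, 1 rose and 1 fell, over all genes and adjusted over the list alone. The calcium-activated chloride channel ANO1 rose 1.16-fold, from 223.9 ± 8.99 to 260.7 ± 2.14 CPM (log2 change 0.22 ± 0.04, edgeR adjusted p = 0.0228), and the epithelial calcium channel TRPV5 fell (edgeR adjusted p = 0.0427). Both calls ended without 37C replicate 2 and without each of the 41C replicates, and 3 members were higher and 2 lower without 37C replicate 3. The list was not apart from other genes (camera adjusted p = 0.202), with a median of 0.05 (0.07 without 37C replicate 1 and 0.02 without 37C replicate 3) and a mean of -0.03, and counting intervals cover counting error only.

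Hedgehog pathway genes did not pass the threshold. PTCH1, the receptor and a common target of the pathway, had 65.2 ± 3.80 CPM at 37C and 75.1 ± 2.47 at 41C (log2 change 0.20 ± 0.06, edgeR adjusted p = 0.116), and the transcription factor GLI3 had a log2 change of 0.31 ± 0.07 (edgeR adjusted p = 0.0547). SMO and GLI1, the signal transducer and a direct target, had log2 changes of -0.03 ± 0.11 and -0.03 ± 0.22 (edgeR adjusted p = 0.951 and 0.974). Adjusted over the list alone, GLI3 and PTCH1 were higher, and 2 of the 15 tested members passed over all genes without 37C replicate 3. The list was not apart from other genes (camera adjusted p = 0.198); its median was 0.13 in counts, 0.07, 0.06 and 0.06 without 37C replicate 1, 37C replicate 3 or 41C replicate 2, and -0.02 with log2(FPKM + 1). The ligand SHH had 0 counts at 37C and 2 at 41C, and GLI2 likewise, so neither can be compared.

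Among secreted factors that stimulate melanocytes, WNT7A and the ErbB ligand NRG1 rose. WNT7A went from 23.1 ± 2.53 to 32.6 ± 0.703 CPM (log2 change 0.49 ± 0.08, edgeR adjusted p = 0.00766) and NRG1 from 112.2 ± 10.3 to 135.9 ± 4.99 CPM (0.28 ± 0.06, edgeR adjusted p = 0.0433). The call of NRG1 ended with the length correction (0.22 ± 0.08, edgeR adjusted p = 0.235), 1 of 9 alternatives where it did. EDN1, which encodes endothelin, was 1.55 times as high at 41C without passing (0.63 ± 0.17, edgeR adjusted p = 0.0826), and KITLG, the ligand of KIT, had a log2 change of -0.04 ± 0.10 (edgeR adjusted p = 0.912). FGF2 had 8 counts over the libraries at 37C and 4 at 41C (ratio 0.48, counting interval 0.11 to 1.79). Of 11 tested members 2 rose and 0 fell, with 3 higher and 2 lower adjusted over the list alone, and the list was not apart from other genes (camera adjusted p = 0.645; median -0.02, mean 0.04). The median was 0.02 without 37C replicate 1 or 37C replicate 2 and -0.07 without 41C replicate 1. The 2 higher genes became 3 without 37C replicate 3, 1 without 41C replicate 1, 1 without 41C replicate 3, and 0 without 37C replicate 2 or 41C replicate 2, and 1 member was lower without 37C replicate 1, without 37C replicate 3 and with DESeq2. Of 8 tested secreted inhibitors of melanogenesis 0 passed over all genes and 1 was higher adjusted over the list alone; TGFB2 had a log2 change of 0.23 ± 0.07 (edgeR adjusted p = 0.124). Their list stood above other genes (median 0.18, camera adjusted p = 0.0447; adjusted p = 0.434 with an estimated correlation), and no longer did without 37C replicate 2 (0.320, median 0.07), without 41C replicate 1 (0.0727, median 0.11) or with the GC correction (0.108); 3 members were higher without 37C replicate 3.

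Genes grouped here after their values were seen, from those with the lowest folds, include some known from stressed or internal epithelia. SERPINB3 fell from 9.48 ± 2.11 to 4.55 ± 0.288 CPM (log2 change -1.06 ± 0.16, edgeR adjusted p = 0.00408), S100A9 from 17.3 ± 4.06 to 8.83 ± 1.33 CPM (-0.97 ± 0.17, edgeR adjusted p = 0.0344) and KRT13 from 40.6 ± 4.4 to 26.1 ± 1.90 CPM (-0.64 ± 0.09, edgeR adjusted p = 0.00170). S100A7 has a close paralog that may share its reads. SERPINB3 and SERPINB4 share long near-identical stretches, and their sum fell by 1.01 ± 0.14 on the log2 scale (edgeR adjusted p = 0.00405). Of 17 tested epidermal differentiation genes only S100A7 passed, over all genes and adjusted over the list alone, and the list was not apart from other genes (median -0.02, camera adjusted p = 0.276). Of 9 stress keratins and wound-edge genes, KRT6A rose 1.16-fold (0.21 ± 0.05, edgeR adjusted p = 0.0421; uncertain beside its near-identical copies) and S100A9 fell. It had 2 higher and 2 lower members adjusted over the list alone and was not apart (camera adjusted p = 0.337; median 0.20, mean -0.05). S100A7 and SERPINB3 lost their calls without 41C replicate 2 (edgeR adjusted p = 0.0666 and 0.0894), S100A9 without any 1 of the 41C libraries, and KRT6A in each fit with 1 library left out except that without 37C replicate 3. In that fit 3 differentiation genes were lower and 1 higher, and 2 stress genes were higher and 2 lower. The stress list's median was 0.09 without 37C replicate 2 and 0.12 without 41C replicate 1, and that of the differentiation list -0.05 without 37C replicate 3 and -0.08 without 41C replicate 3.

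Of 24 tested interferon-stimulated genes 1 fell, IFIT1, from 71.3 ± 3.20 to 59.6 ± 0.927 CPM (log2 change -0.26 ± 0.06, edgeR adjusted p = 0.0386), and 20 had a negative log2 change. There were 5 lower adjusted over the list alone (median -0.11, camera adjusted p = 0.000125; adjusted p = 0.309 with an estimated correlation). That median was -0.20 without 37C replicate 1 and -0.07 with the length correction. Of 19 NF-kB cytokines and chemokines 1 fell, the acute-phase gene SAA1, from 108.2 ± 3.06 to 87.4 ± 3.82 CPM (-0.31 ± 0.05, edgeR adjusted p = 0.00823), and 3 were lower adjusted over the list alone (median -0.14, camera adjusted p = 0.000690; adjusted p = 0.151 with an estimated correlation). With the length correction 0 NF-kB genes passed, the list lost its call (0.155) and so did SAA1 (edgeR adjusted p = 0.110). The chemokine CXCL3 had a log2 change of -0.79 ± 0.20 (edgeR adjusted p = 0.0707). Without 37C replicate 3, 4 interferon-stimulated and 5 NF-kB genes were lower. The interferon count was 0 without 37C replicate 2 or any 1 of the 41C libraries, and the NF-kB count 0 without 37C replicate 2, 41C replicate 1 or 41C replicate 2.

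Of 26 tested G2/M genes 3 fell and 25 had a negative log2 change, with a median of -0.13 that was -0.20 without 37C replicate 3. UBE2C, a ubiquitin enzyme of mitotic exit, fell from 177.7 ± 6.95 to 145.5 ± 10.8 CPM (log2 change -0.29 ± 0.06, edgeR adjusted p = 0.0192, and 0.0587 with the length correction), the mitotic cyclin CCNB1 from 283.0 ± 6.12 to 240.1 ± 12.9 CPM (-0.24 ± 0.05, edgeR adjusted p = 0.0212), and its kinase CDK1 from 114.9 ± 11.3 to 92.8 ± 3.53 CPM (-0.31 ± 0.07, edgeR adjusted p = 0.0384). There were 7 lower adjusted over the list alone (camera adjusted p = 1.14e-10; adjusted p = 0.306 with an estimated correlation). The count of 3 was 14 without 37C replicate 3 and 0 without 37C replicate 2, 41C replicate 1 or 41C replicate 2. Of 26 G1/S genes 0 passed over all genes or adjusted over the list alone, and the list was not apart (camera adjusted p = 0.438), with a median of 0.01 that turned to -0.01 with upper-quartile scaling or without 37C replicate 2 and was 0.03 without 37C replicate 3, without 41C replicate 2 and with the length correction; 3 members were higher without 37C replicate 3.

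**Figure D3:**
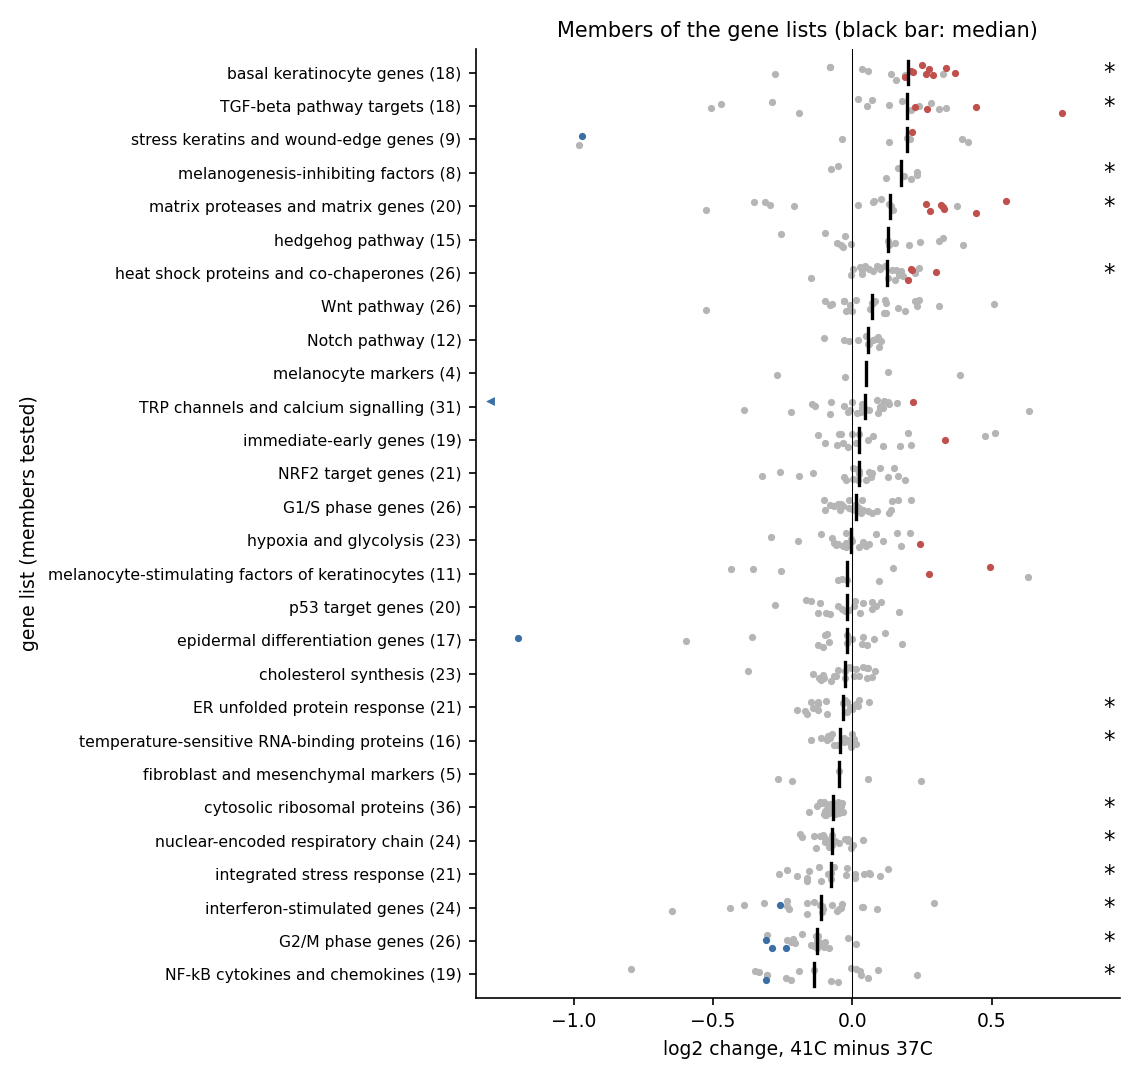
Log2 change at 41C against 37C (horizontal) of the tested members of 28 gene lists (vertical, number tested in brackets), with members that passed the edgeR threshold in red when higher and blue when lower, black bars at list medians, an asterisk where camera passed with the preset correlation, and a triangle for TRPV5, which lies beyond the axis. Medians ran from -0.14 for NF-kB genes to 0.20 for basal keratinocyte genes.

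The abundance of long and short genes differed between libraries. The log2 change at 41C rose with gene length across genes (Spearman rho 0.254, over genes, which are not independent replicates), and 0.07 remained without 37C replicate 3. That library's expression fell with gene length, from a median deviation of 0.10 in the shortest of 10 equal bins of genes to -0.10 in the longest. Higher genes had a median length of 7057 bases and lower genes 2368.5, against 4038 for all tested genes. After each library was corrected for its length trend, 114 genes passed, 78 higher and 36 lower, and 86 of the 131 were among them. Cytosolic ribosomal proteins, with a median length of 1105 bases, had 36 of 36 log2 changes below 0 (median -0.07, 0 past the threshold over all genes or adjusted over the list alone, camera adjusted p = 4.79e-09; adjusted p = 0.416 with an estimated correlation) and turned to a median of 0.01 after the correction. Without 37C replicates 1 and 3 in turn their median was -0.11 and -0.04, and that of the respiratory chain list was -0.05 without 37C replicate 3. The nuclear-encoded respiratory chain had 0 of 24 past the threshold over all genes and 1 lower adjusted over the list alone (median -0.07, camera adjusted p = 3.45e-05; adjusted p = 0.309 with an estimated correlation), and was no longer apart after the correction (0.457; from 1.74e-06 to 0.584 over the alternatives). The unfolded protein response, NF-kB, integrated stress response and temperature-sensitive lists also lost their calls with it (0.0777, 0.155, 0.127 and 0.0691), with medians of -0.04, -0.13, -0.05 and -0.03 after it. The basal, matrix and heat shock lists had 9, 6 and 5 higher genes after it, of which 8, 6 and 4 were among those called before. Of the named genes, 7 lost their calls with the correction. The log2 changes of 5 moved by less than their standard errors, to 0.40 ± 0.10 for NAV3, -0.52 ± 0.13 for POMZP3, -0.33 ± 0.08 for SIGIRR, 0.23 ± 0.06 for NDRG1 and 0.22 ± 0.08 for NRG1, from 0.45 ± 0.10, -0.58 ± 0.13, -0.37 ± 0.08, 0.24 ± 0.05 and 0.28 ± 0.06 (edgeR adjusted p = 0.0643, 0.0618, 0.0514, 0.0832 and 0.235). They became smaller for UBE2C and SAA1, at -0.22 ± 0.05 and -0.18 ± 0.05, from -0.29 ± 0.06 and -0.31 ± 0.05 (edgeR adjusted p = 0.0587 and 0.110).

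**Figure D4:**
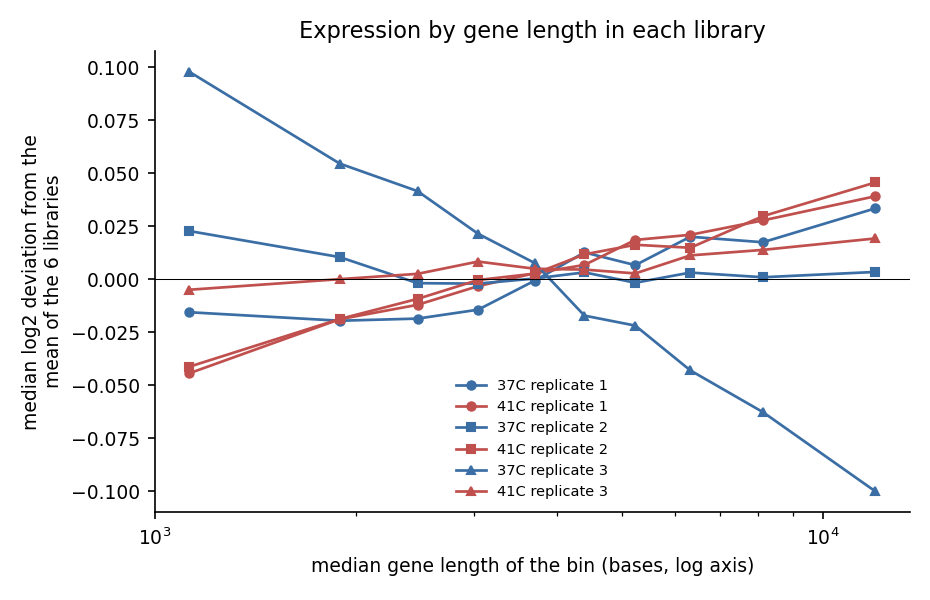
Median log2 deviation from the mean of the 6 libraries (vertical) in 10 equal bins of the tested genes by gene length (horizontal, bases, log axis), with 1 line per library, 37C in blue and 41C in red. 37C replicate 3 ran from 0.10 to -0.10, farther than any other library.

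Metabolic and signalling lists held few genes past the threshold. The hypoxia gene NDRG1 rose 1.18-fold (log2 change 0.24 ± 0.05, edgeR adjusted p = 0.0427), alone among 23 hypoxia and glycolysis genes over all genes, with 2 higher adjusted over the list alone (camera adjusted p = 0.681); of the fits with 1 library left out it passed in that without 37C replicate 3, where 2 members were higher. JUN, a subunit of the AP-1 transcription factor, rose 1.26-fold (0.33 ± 0.07, edgeR adjusted p = 0.0401), alone among 19 immediate-early genes over all genes and adjusted over the list alone (camera adjusted p = 0.132); it passed without 37C replicate 1 or 37C replicate 3, and the latter fit had 2 higher members and put the list above other genes (camera adjusted p = 0.0324; adjusted p = 0.349 with an estimated correlation), as did the length correction (0.0155; adjusted p = 0.376 with an estimated correlation). None of the 20 p53 target genes, 21 NRF2 target genes, 23 cholesterol synthesis genes, 26 Wnt pathway genes and 12 Notch pathway genes passed edgeR's test over all genes or adjusted over the list alone (0 in each list), and camera gave adjusted p = 0.575, 0.615, 0.231, 0.141 and 0.231. Fry put the Wnt list above 0 (adjusted p = 0.0323). Without 37C replicate 3, 2 Wnt genes and 1 NRF2 target were higher and 1 cholesterol gene was lower, while 1 Wnt gene and 1 NRF2 target were lower without 37C replicate 1. With the GC correction 1 Wnt gene was higher and 1 NRF2 target lower. The NRF2 list stood above other genes without 37C replicate 3 or 41C replicate 3 (camera adjusted p = 0.0470 and 0.0446; 0.0147 with the length correction without 37C replicate 3) and the cholesterol list below them without 41C replicate 2 (0.0380). With an estimated correlation in these fits the NRF2 list had adjusted p = 0.551, 0.503 and 0.614 and the cholesterol list 0.485.

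Markers of other cell types did not pass the threshold. Of 4 tested melanocyte markers 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.645), and PMEL had 2.22 ± 0.374 CPM at 37C and 2.18 ± 0.699 at 41C. The 5 tested fibroblast and mesenchymal markers gave 0 calls over all genes or adjusted over the list alone (camera adjusted p = 0.866), with FBLN1 at 24.7 ± 1.79 and 23.9 ± 0.995 CPM, COL3A1 at 11.8 ± 1.52 and 14.0 ± 1.19, and COL1A1 at 2.69 ± 0.101 and 2.31 ± 0.129. Of the immune cell markers 2 were tested and 0 passed, and no list test was made; CD68 had 15.3 ± 2.0 and 15.1 ± 1.72 CPM. On GRCh38, PMEPA1 lies on chromosome 20 at 57648392 to 57711536, TNC on chromosome 9 at 115019578 to 115118257, and LAMA3 on chromosome 18 at 23689443 to 23956222. S100A7 and S100A9 lie on chromosome 1 at 153457744 to 153460701 and 153357854 to 153361027, and SERPINB3 and SERPINB4 are neighbours on chromosome 18, at 63655197 to 63661963 and 63637259 to 63644298. HSPA1A and HSPA1B are neighbours on chromosome 6, at 31815464 to 31817946 and 31827735 to 31830255.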

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

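The corrections for gene length and GC content, and the estimated correlation in fits other than the main one, were chosen after the data had been examined. None of the 131 changed genes turned its sign under any alternative that gave it a value, and 0 of the 47 named genes past the threshold reversed. The groups of each of the 131 did not overlap, so their selection largely set this outcome. Of the named genes not past the threshold, 11 changed sign somewhere. None of the 47 stayed past the threshold under all 19 alternatives, and limma on log2(FPKM + 1) without a filter called 0 genes while 1888 had an unadjusted p under 0.05. CLU, KRT13, MYH9 and PMEPA1 lost their calls there alone, and the rest of the 47 in 2 to 11 settings. KRT13 had an adjusted p in only 18 of the 19 alternatives. The count of changed genes rose from 131 to 253 with DESeq2 (185 higher, 68 lower; 98 shared), 284 without a filter (184 and 100), and 442 with the GC correction (322 and 120). It was 40 (22 and 18) and 41 (22 and 19) with limma on log2(FPKM + 1) and log2(FPKM + 0.1). With 1 library left out it ran from 5 to 805, and the length correction without 37C replicate 3 gave 1029 (733 and 296). Limma-voom, DESeq2 scaling, upper-quartile scaling, the stricter filter and the length correction gave 123, 133, 110, 128 and 114.

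The 4 genes changed at least 2-fold became 0 with DESeq2, where the adjusted p of S100A7 is not given after independent filtering. They became 8 without a filter, 2 with the stricter filter, 1 with log2(FPKM + 1), 2 with log2(FPKM + 0.1), 0 with log2(FPKM + 1) without a filter, 7 with the GC correction and 20 with the length correction without 37C replicate 3. With 1 library left out they ran from 0 to 20. With the replicate block 438 genes passed (297 and 141), 8 of them at least 2-fold. The labels state no pairing by replicate number. The deviations of same-numbered libraries correlated at 0.082, -0.019 and 0.077 over genes. Those of differently numbered libraries of the 2 groups correlated at -0.14 to 0.066. In the simulated data, drawn without pairing, the block gave 142 calls, against 148 without it. These values do not settle whether the samples were paired. The cause of these moves was not tested, except that fewer libraries or fewer genes entered some fits.

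Of 28 lists, 13 passed with camera, 5 higher and 8 lower. With an estimated correlation 1 passed, the basal keratinocyte list, and 0 passed with it in each of the other fits tried (basal list 0.0536 to 0.376). The estimate was 0.376 for G2/M genes and 0.748 for ribosomal proteins, but 0.00521 for the basal list and -0.0339 for NF-kB genes. The latter estimates lie below the preset 0.01. For the basal and NF-kB lists, stronger correlation between members therefore does not account for the higher adjusted p. A missed call with an estimated correlation is thus not in itself a sign of correlated members. With the replicate block the basal list had a camera adjusted p = 1.57e-13 at the preset correlation and 0.376 with an estimated one. With fry 5 lists passed (4 higher, 1 lower), among them the Wnt list (0.0323), which camera did not call. The length correction put the ribosomal protein list above other genes (adjusted p = 1.29e-05; 0.000209 without 37C replicate 3; with an estimated correlation 0.196 and 0.166) and left the respiratory chain list not apart (0.457 and 0.584), its median at -0.02 after the correction. The depth leaves genes such as TRPV3, SHH and FGF2 at few counts.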

Other observations

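The focal adhesion list, the tests of G1/S genes and the corrections for gene length and GC content were chosen after the changed genes had been seen. Some changed genes belong to focal adhesions and the actin cytoskeleton, a group that no list fixed before the data were examined covers. Because they had been seen, a list of 54 such genes was drawn up; 51 were tested, 11 rose and 0 fell. The non-muscle myosin gene MYH9 rose by 0.37 ± 0.04 on the log2 scale (edgeR adjusted p = 0.000572), the actin crosslinker FLNA by 0.33 ± 0.05 and the integrin ITGB5 by 0.29 ± 0.05 (edgeR adjusted p = 0.00408 and 0.00823). VCL, ACTN1 and ITGA5 rose too. Of these genes, FLNA, ITGB5, VCL and ACTN1 were chosen after their values were seen. The count of 11 was 17 without 37C replicate 3 and 1 without 37C replicate 2, and 4, 1 and 3 without 41C replicates 1, 2 and 3, while the median over all members stayed between 0.114 and 0.151 in the fits with 1 library left out. The hypothesis that the rest of the group moved as well was tested on the 40 members that had not passed. Of these 34 had a positive log2 change, with a median of 0.106 (95% bootstrap interval over members 0.068 to 0.141), and 0.099 after the length correction (0.081 to 0.128). This is consistent with a small rise of further members, but the list was drawn up after the data had been seen, and members share regulation, so the interval is too narrow. With the length correction 7 members passed. Camera over all 51 members, with an estimated correlation, gave p = 0.00782, and p = 0.073 after the length correction, where the list no longer stood apart. As the members that prompted the list are among the 51, the first value is no support for a rise of the group.

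The split into temperatures called 131 genes, and the highest of the other splits of the 6 libraries into 3 and 3 called 2. The real split was the 1 of 10 with as many genes, and 10 splits are too few for a share under 0.05.

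The first pattern is the rise of 19 genes of the matrix, TGF-beta target and basal keratinocyte lists, all past the threshold. Besides matrix and laminin genes they include EGFR, KRT14 and integrin genes. If the length trend of the libraries were the cause of this rise, the correction should remove it. Over these genes the median log2 change was 0.277 before and 0.286 after the length correction, a ratio of 1.03 (0.895 to 1.099), and the GC correction gave a ratio of 1.01. The 19 genes had been picked as past the threshold and higher. Their selection thus largely set these ratios, and no conclusion is drawn from them. Over all tested members of the basal, matrix and TGF-beta lists, the medians were 0.20, 0.14 and 0.20 before the length correction. They were 0.21, 0.16 and 0.19 after it, which argues against the length trend as the whole cause of these list medians. A response of the cells to 41C, which the design names, may underlie the pattern. A difference in culture density or handling between the groups stays open, since no table here measures it.

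The second pattern is the negative median of the G2/M list, of which 3 members passed. The ratio of the corrected to the uncorrected median over 26 members was 0.971 with the length correction (0.766 to 1.065) and 0.93 with the GC correction, which argues against both trends. A smaller share of cycling cells would lower G1/S genes as well, and their median was 0.013 (-0.023 to 0.046) beside -0.125 for G2/M genes. With 1 library left out it ran from -0.01 to 0.03. The G1/S median thus did not fall with that of the G2/M genes. Members share regulation, with estimated correlations of 0.115 for G1/S and 0.376 for G2/M genes, so the interval of the G1/S median is too narrow. With an estimated correlation the G2/M list was not apart from other genes (camera adjusted p = 0.306). The values do not decide between a shift within the cycle and fewer cycling cells. Cell cycle phases were not measured, and the time since the last exposure stays open.

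The third pattern is the fall of S100A7, S100A9, SERPINB3, SERPINB4 and KRT13, grouped after their values were seen. If 1 library at 37C had carried it, leaving that library out would have removed it. The lowest ratio of their median change without 1 of these libraries to that with all was 0.796, with the median going from -0.969 to -0.771. These genes were drawn from those past the threshold whose groups did not overlap. Their selection thus largely set this outcome, and no conclusion is drawn from it. If the whole differentiation programme had shifted, the other 16 differentiation genes would have fallen alike, and their median was -0.019 (-0.098 to 0.038). Of 43 listed differentiation genes 17 were tested, so these values cover that part of the programme alone. A small number of cells that express these genes strongly, in different shares in the groups, could give the pattern. Bulk libraries do not test that.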
